A study of Mus musculus with 4 samples.

How the data were processed

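RNA was measured by sequencing in isolated pancreatic islets of C57BL/6 mice of 2 genotypes, wild type (WT) and KR mutant, in 2 feeding states, fasted and refed. Each of the 4 combinations of genotype and feeding state has 1 library. Per the labels' protocols, islets of 3 WT and 3 KR mice were combined per genotype before RNA isolation, so each library is a pool and the design holds no biological replicate. The sample titles give a fast of 48 h, followed in the refed samples by 6 h of refeeding, whereas the extraction protocol in the labels gives a fast of 24 h. Both are stated here because the labels do not settle the difference. Poly-A selection and an Illumina TruSeq preparation were used, per the labels' protocols.

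The reads were demultiplexed with bcl2fastq 1.8.4 and aligned with TopHat2 2.0.4 to mouse build mm9, per the submitters' processing notes. The deposited values are FPKM, a number of fragments scaled by transcript length and by the library total, per the file headers, with a lower and an upper bound and a status for each gene. The program that made the FPKM values, its annotation release and the total each library was scaled by are not given in the sources used here. Each table holds 23699 rows. Rows with the same symbol were summed, which gave 23235 symbols. Values with a status other than OK were treated as missing, and 189 symbols lacked a value in at least 1 library. Among these is Ins2 in the fasted KR library, which is listed at 0 with the status for too many fragments, so its level there was not measured. Coordinates are those of mm9 as deposited, written as counted from 1. Where they were tested on 631 microRNA rows, the deposited length equalled the end minus the start in 601 and the end minus the start plus 1 in 14, so a start may lie 1 base before the first base of the gene.

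Depth was estimated from the deposited bounds. For each gene the squared ratio of the FPKM to its standard error, taken as the upper bound minus the FPKM divided by 2, gave an implied number of fragments. This number lay within 0.05 of a whole number for 75.2%, 75.3%, 74.6% and 74.5% of genes with under 100 implied fragments in the fasted WT, fasted KR, refed WT and refed KR libraries. The implied fragments summed to 26407398, 25711229 without Ins2, 18096754 and 11074797, in the same order. The depths relative to the fasted WT library were 1.01 in fasted KR, 0.683 in refed WT and 0.418 in refed KR, from 7982 genes with over 200 implied fragments. The refed libraries were therefore the shallower ones in both genotypes. Genes listed at 0 numbered 6641, 6490, 6881 and 7228.

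All comparisons used log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. The 11953 genes with a mean FPKM of at least 1 over the 4 libraries and a value in each were tested. For each pair of libraries the log2 ratio was computed per gene, and genes at least 2-fold apart were counted without a p-value, since a difference between 2 libraries has no replicate check. The effects shared across the design were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, in the additive model of feeding state and genotype. This leaves 1 residual degree of freedom per gene and counts the interaction as error. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Each gene's variance, on 1 residual degree of freedom, is combined with a prior from all tested genes worth 7.58 degrees of freedom. The p-values therefore rest mostly on the spread of other genes, and only on that between these pooled libraries. They take the genotype effect to be the same in both feeding states. The errors given with fitted log2 changes are the moderated standard errors of this model over the 4 libraries. They can be smaller than a gene's own spread between libraries.

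Gene lists for islet cell types, metabolism and stress pathways, 31 in all, were fixed in advance. For the 26 lists with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is no test of the conditions. Counts of list members that rose or fell use the limma test over all genes, and a further count uses p-values adjusted over the list alone. The genes named are a fixed panel, the 8 highest and 8 lowest ratios of each pairwise contrast, the 8 largest changes in each direction shared by both contrasts, and list members past the threshold or at least 2-fold apart. The ranked parts of this rule take genes with a mean FPKM of at least 5 and leave out unnamed and small RNA genes. Genes named outside the rule are said to be chosen after their values were seen. Some genes that the rule names are not reported here.

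The additive model was tested on simulated data for the genotype comparison, with 50 genes changed at each of 4 sizes among 11953. It recovered 88% of those changed by 0.5 on the log2 scale and 100% of those changed by 1, 1.5 or 2. Of its 203 calls 9 were false, and with no effect simulated it made 2 genotype calls and 0 feeding calls. These rates hold for the simulated data only, and whether its noise resembles that between these libraries was not tested. On the deposited data the genotype calls ran from 0 to 892 over the alternatives listed below. The placement of list medians was tested on simulated lists of 25 members in the fasted KR to WT contrast. It put 20 of 20 lists shifted by 0.3, and 1 of 20 unshifted lists, outside the central 95% of random lists.

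The alternatives were pseudocounts of 0.1 and 5, no filter or a mean FPKM of at least 5, fold thresholds of 1.5 and 4, rescaling of the libraries by the median of ratios, and limma without trend or with a robust prior. In a further alternative acinar genes were left out and the remaining genes with a value in each library were rescaled to a common total. This left out Ins2 as well. The groups, tests, gene lists, naming rule and these alternatives were chosen before the data were examined. Leaving out the 36 small RNA genes tested and running limma-voom on the implied fragments were added after the data were seen. Transcript lengths for a check of length bias came from the GENCODE M21 reference on another build, which was used for no coordinates and gave a length for 99.1% of the tested genes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for the remaining steps. Genes that share reads with near-identical copies, among them ribosomal protein genes with processed pseudogenes and the insulin pair, are uncertain, as are overlapping genes, since the handling of such reads and of strand is not given in the sources used here.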

Results

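Gene expression was measured by RNA sequencing in pooled pancreatic islets, the clusters of hormone-secreting cells of the pancreas, from wild type (WT) mice and from KR mutant mice. KR is known from the study as a knock-in of the transcription factor FoxO1 in which acetylated lysines are replaced by arginine, and the series asks how the acetylation of FoxO1 bears on fatty acid oxidation and insulin secretion in beta cells. The 4 groups, fasted WT, fasted KR, refed WT and refed KR, hold 1 pooled library each. Per the deposited bounds, the depth relative to fasted WT was 1.01 in fasted KR, 0.683 in refed WT and 0.418 in refed KR, where fasted WT held about 26407398 fragments. Because no group has a replicate library, no difference between 2 single libraries has a replicate check.

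Foxo1, the gene that carries the KR change, lies on chromosome 3 at 52072259 to 52154031 and was expressed in every library. Its FPKM was 17.4 in fasted WT (bounds 16.7 to 18.2), 14.1 in fasted KR (13.5 to 14.8), 18.8 in refed WT (17.9 to 19.6) and 13.8 in refed KR (12.8 to 14.7). The fitted difference between KR and WT was -0.35 ± 0.07 (SE) on the log2 scale, and it did not pass the limma test (adjusted p = 0.0667). Over 10 alternatives the adjusted p of that test ran from 6.9e-06 to 0.419 and passed in 4, so whether Foxo1 is lower in KR stays undecided. A knock-in that changes the protein need not remove the transcript, so the level of Foxo1 checks nothing about the genotype labels.

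The comparison of KR with WT islets asks which transcripts follow the state of FoxO1. Among beta-cell genes the largest shared difference was in Ins1, which encodes insulin I and lies on chromosome 19 at 52338813 to 52339948. Its FPKM was 4320 in fasted WT and 7966 in fasted KR, and 3498 in refed WT and 12196 in refed KR. Ins1 thus rose in KR in both feeding states, by 1.34 ± 0.16 (SE, 4 libraries) on the log2 scale (adjusted p = 0.00792). Over 10 alternatives the adjusted p of Ins1 ran from 2.4e-88 with limma-voom to 0.518 with a robust prior, and Ins1 passed in 7 of them, losing its call there, without trend and with no filter on low values. Ins2, which encodes insulin II and lies on chromosome 7 at 149864561 to 149865613, had an FPKM of 121397 in refed WT and 201043 in refed KR, a log2 ratio of 0.73 that has no test. In fasted WT the FPKM of Ins2 was 122864, and its level in fasted KR was not measured. The FPKM of Ins1 was 3.52% of that of Ins2 in fasted WT, 2.88% in refed WT and 6.07% in refed KR.

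Of the 26 measured genes of beta-cell identity and maturity, 7 rose in KR, none fell and 19 did not pass the test. Adjusted over the list alone, 12 rose and 0 fell. In limma without trend, and with no filter on low values, 0 of the 7 were called. Slc2a2, the glucose transporter of the beta cell on chromosome 3 at 28596825 to 28627282, rose by 0.69 ± 0.08 (adjusted p = 0.00528), from an FPKM of 47.3 to 85.4 in the fasted and from 108 to 158 in the refed islets. G6pc2, an islet glucose-6-phosphatase on chromosome 2 at 69058055 to 69066045, rose by 0.62 ± 0.06 (adjusted p = 0.00325), with an FPKM of 221 and 366 in fasted and 542 and 776 in refed WT and KR islets. Iapp, which encodes amylin, rose by 0.36, Trpm5 by 0.40, Ucn3, a marker of mature beta cells, by 0.30 and the zinc transporter gene Slc30a8 by 0.29. Mafa, a transcription factor of mature beta cells, had a log2 ratio of 0.93 in the fasted and 0.16 in the refed pair, and its shared difference of 0.54 ± 0.14 did not pass (adjusted p = 0.123). Nor did Pdx1, at 0.29 ± 0.09, or Nkx6-1, at 0.02 ± 0.07. The median log2 ratio of the list was 0.23 in the fasted and 0.11 in the refed pair, at percentile 100 of the random lists in each. With 1 pooled library per group, a larger share of beta cells in the KR pools cannot be told apart from a change within these cells.

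**Figure D1:**
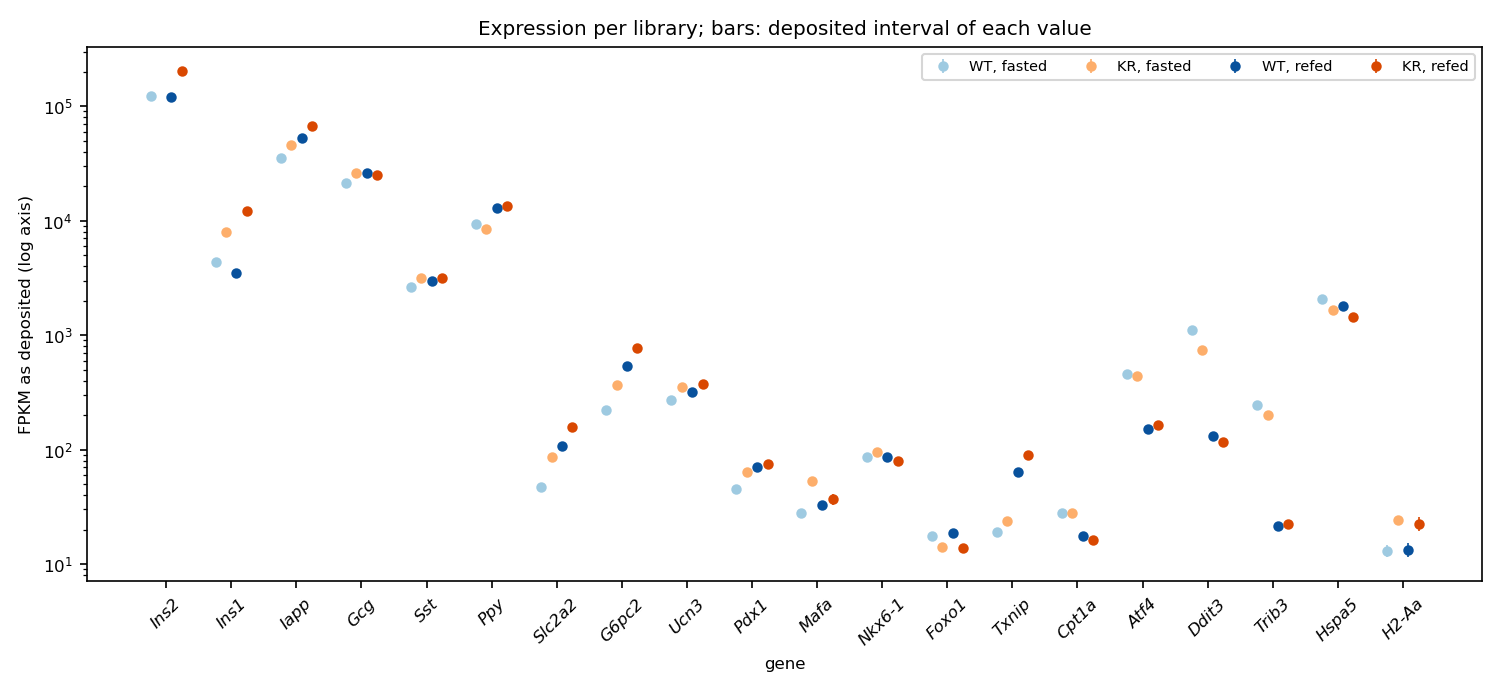
FPKM of 20 genes in each of the 4 pooled libraries on a log axis, 1 point per library, with the deposited bounds of each value as bars that are mostly smaller than the points. Ins1 stands at 3498 in refed WT and 12196 in refed KR, Trib3 at 245 in fasted WT and 21.6 in refed WT, and Ins2 has no point for fasted KR because it was not measured there.

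The insulin granule and exocytosis list, 26 genes, held 2 genes that rose, Pcsk2, a prohormone convertase, by 0.32 and Slc30a8, and 0 that fell, with 5 and 0 adjusted over the list alone. Its median ratio was 0.05 in both pairs, at percentiles 99.9 and 100. Of the 16 measured alpha, delta and PP cell genes, the retinol-binding protein gene Rbp4 rose by 0.50 ± 0.07 (adjusted p = 0.0113), 0 fell and 15 did not pass, with 1 and 0 adjusted over the list alone. Glucagon (Gcg) stood at an FPKM of 21258 and 26030 in fasted and 26161 and 24882 in refed WT and KR islets, and neither it nor somatostatin (Sst) passed the test. The median of this list was 0.20 in the fasted pair, at percentile 100, and 0.06 in the refed pair, at percentile 99.5. Among 10 measured progenitor and dedifferentiation genes only Serpina7, the thyroxine-binding globulin gene, passed, with a fall of -0.51 ± 0.07 (adjusted p = 0.0113), and the count adjusted over the list alone was 0 up and 1 down. Neurog3, an endocrine progenitor factor, had an FPKM of 7.30, 9.95, 9.73 and 9.08 in fasted WT, fasted KR, refed WT and refed KR, and Aldh1a3, a marker of failing beta cells, lay under 1 in each library, at 0.509 or less.

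None of the 32 measured fatty acid oxidation genes passed the genotype test over all genes. Adjusted over the list alone, 2 were higher and 3 lower in KR. Cpt1a, which encodes the rate-limiting carnitine transferase of the pathway, had an FPKM of 28.1 in both fasted libraries and of 17.5 in refed WT and 16.2 in refed KR, with a shared difference of -0.05 ± 0.07. Pdk4, a kinase that restrains pyruvate oxidation, was at -0.07 ± 0.08, and Ppara lay at an FPKM of 0.459 or less in each library. The median ratio of the list was -0.0043 in the fasted pair, at percentile 89.3, and -0.09 in the refed pair, at percentile 17.7. The fasted value turned to 0.021 after rescaling by the median of ratios, which moved all genes alike, and relative to all genes it was 0.026 before and 0.028 after. Of 27 measured FoxO target genes, Txnip, a thioredoxin inhibitor, rose by 0.42 ± 0.07 (adjusted p = 0.0289), Eif4ebp1, a translation repressor, fell by 0.37 ± 0.06 (adjusted p = 0.0278) and 25 did not pass, with 1 up and 3 down adjusted over the list alone. Their median ratios were -0.04 and -0.05, at percentiles 40.6 and 53.5.

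Among 18 genes of fatty acid and triglyceride synthesis, Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, rose by 0.53 ± 0.06 (adjusted p = 0.00523) and 0 fell, with 1 and 2 adjusted over the list alone. None of 22 cholesterol synthesis genes passed, and 1 fell adjusted over the list alone, at list medians of -0.10 in the fasted and -0.17 in the refed pair, percentiles 0.95 and 0.08. Of 47 oxidative phosphorylation genes 0 passed, with 0 up and 1 down adjusted over the list alone, and of 30 glycolysis and TCA cycle genes 0 passed, with 1 up and 0 down. Of 10 measured beta-cell disallowed genes, which other tissues express and beta cells keep low, 0 passed by either count.

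The ATF4 and amino acid response list, 25 genes, held 4 that fell in KR and 0 that rose, with 7 and 0 adjusted over the list alone. These were the stress protein gene Nupr1, at -0.38, the mitochondrial folate enzyme genes Aldh1l2, at -0.41, and Shmt2, at -0.35, and Eif4ebp1. The list median was -0.22 in the fasted pair, at percentile 0, and -0.09 in the refed pair, at percentile 21.1. Hspa5, which encodes the endoplasmic reticulum chaperone BiP, fell by 0.32 ± 0.05 (adjusted p = 0.02) and was the single member of 25 in the unfolded protein response list to pass, with 0 up and 8 down adjusted over the list alone. Of 15 glucocorticoid and fasting response genes, the lipocalin gene Lcn2, at -0.68 ± 0.06 (adjusted p = 0.00251), and the metallothionein gene Mt2, at -0.30, fell, with 5 down adjusted over the list alone. Lcn2 was also the single one of 9 inflammatory genes to pass, with 1 up and 1 down adjusted over the list alone. None of 16 immediate early genes, 19 circadian clock genes or 16 interferon response genes passed by either count. None of 13 cell cycle genes passed, and 1 fell adjusted over the list alone.

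Markers of other cells moved with genotype too. Of 18 measured macrophage and antigen presenting cell genes, H2-Aa, by 0.77 ± 0.07 (adjusted p = 0.00282), H2-Ab1, by 0.65, and Cd74, by 0.53, which encode the class II antigen presentation machinery, rose in KR and 0 fell, with 6 and 2 adjusted over the list alone. The list median was 0.11 and 0.18 in the fasted and refed pairs, at percentiles 99.99 and 100. Of 5 measured lymphocyte genes, the B-cell receptor gene Cd79a, by 0.84, and Cd52, by 0.70, rose, with 3 up adjusted over the list alone, at medians of 0.98 and 0.42. The adipocyte list had 4 measured members, of which the fatty acid binding protein gene Fabp4, at -1.24, and the lipoprotein lipase gene Lpl, at -0.37, fell, with 3 down adjusted over the list alone. The 9 measured endothelial genes had medians of -0.44 and -0.16, at percentiles 0 and 3.4, and 0 passed by either count. Of the 9, 0 were higher in KR in the fasted and 1 in the refed pair. Of 16 stellate cell and fibroblast genes 0 passed, with 2 up and 1 down adjusted over the list alone, and of 11 duct genes 0 passed, with 0 up and 2 down. The acinar list had 6 measured members out of 41, led by Cela1 at an FPKM of 35.0 to 57.4, and 0 passed, with 1 up adjusted over the list alone. Th, which encodes tyrosine hydroxylase, rose by 0.55 among 3 measured neuron and glia genes. Of 4 measured Y-linked genes 0 passed, and 1 fell adjusted over the list alone. The red blood cell list had 1 measured gene, which did not pass, and the mitochondrial genome list 0.

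Further genes with the largest shared differences were the adenosine receptor gene Adora2b, which rose by 0.82 ± 0.07 (adjusted p = 0.0026), the folate receptor gene Folr1, by 0.75, Tmem59l, by 0.73, and the lipid receptor gene Gpr119, by 0.69. Nrip2, by 0.90 ± 0.08 on the log2 scale (adjusted p = 0.00251), the peptide receptor gene Vipr2, by 0.85, S100a4, by 0.76, and the glutathione transferase gene Gsto1, by 0.72, were lower in KR, as were the snoRNA host genes Snhg9, by 0.98, Snhg6, by 0.81, and Snhg1, by 0.64. Rps27, at an FPKM of 90.2 and 18.7 in fasted and 117 and 21.7 in refed WT and KR islets, had the lowest value of the 45 ribosomal protein genes, -2.30 ± 0.07 (adjusted p = 9.59e-07). Reads of Rps27 and of its near-identical copies are hard to tell apart, so this value is uncertain. Rps27 was the single ribosomal protein gene to pass, and the count adjusted over the list alone was 1 up and 1 down.

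In all, 151 of 11953 genes passed the limma test between genotypes, 72 higher and 79 lower in KR, and 12 of them differed at least 2-fold. At an unadjusted p under 0.05 there were 1955. The pairwise counts were small: 29 genes differed at least 2-fold in the fasted pair (16 higher, 13 lower in KR), 12 of them small RNA genes, and 44 in the refed pair (20 higher, 24 lower), 21 of them small RNA genes. Of these, 11 moved in the same direction in both pairs, 6 higher and 5 lower, against 0.0268 and 0.0261 for independent lists. In opposite directions moved 3, all small RNA genes, against 0.0539 for independent lists. Since both numbers exceed independent lists, such an excess is by itself no sign of a shared effect. Besides Fabp4 and Rps27 the 11 were Cldn11, Cnr1, Cxcl13, Xlr4a, Pisd-ps1 and 4 small nucleolar RNA genes, named after their values were seen. Across genes the ratios of the 2 pairs had a Pearson r of 0.26 and a Spearman rho of 0.28, and genes are not independent replicates. The number of calls depends on the model: limma without trend called 5 genes and the test with no filter on low values 0, beside 1892 at an unadjusted p under 0.05, while limma-voom on the implied fragments called 892. Of the list members that passed between genotypes, Fabp4 and Rps27 alone were also called without trend. With the libraries rescaled by the median of ratios 137 were called, 62.8% of them higher in KR, against 47.7% as deposited.

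**Figure D2:**
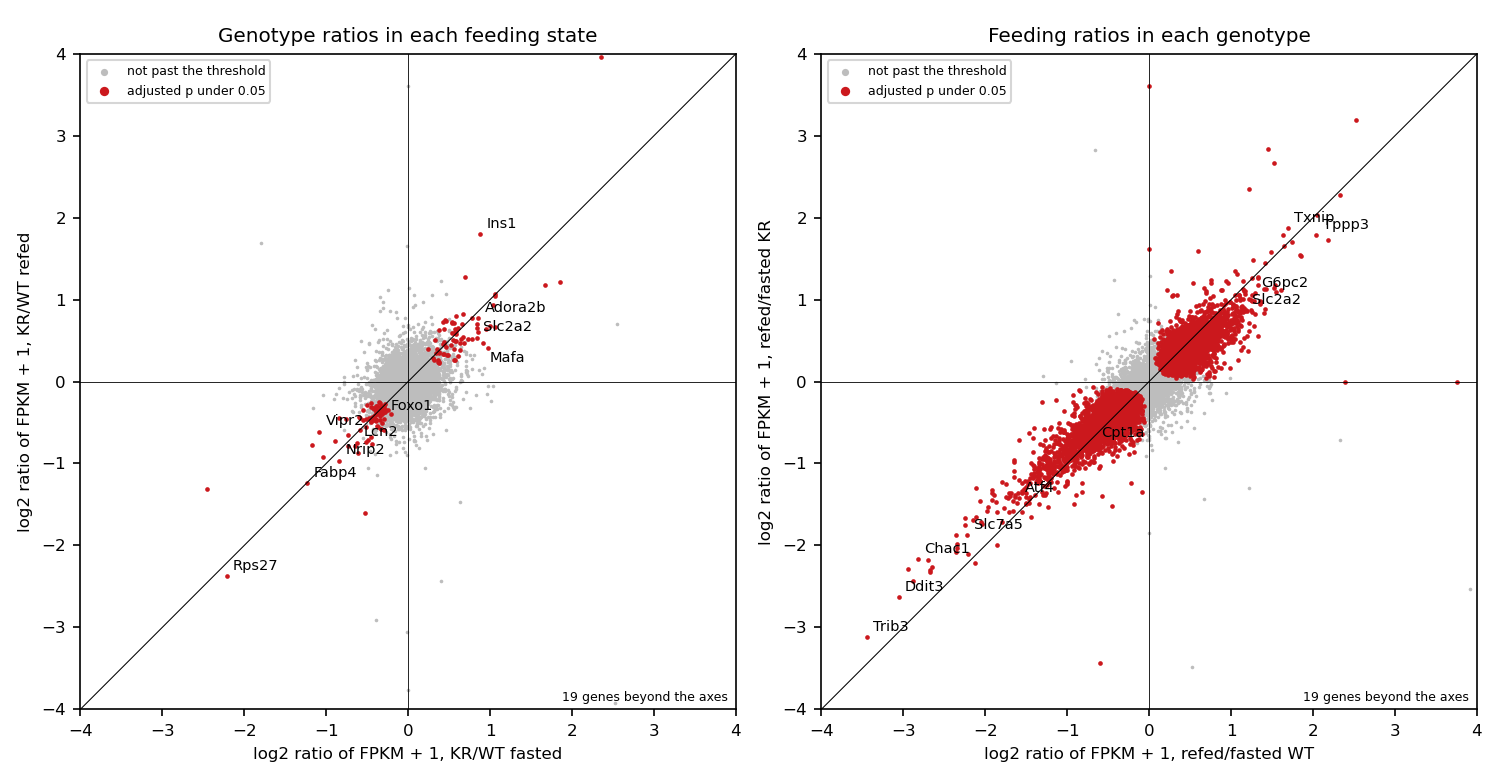
Log2 ratios of FPKM + 1 for 11953 genes, with KR over WT in the fasted against the refed pair on the left and refed over fasted in WT against KR on the right, 1 point per gene, red where the limma adjusted p was under 0.05. The feeding ratios lie along the diagonal (Pearson r 0.78 across genes) more closely than the genotype ratios (0.26), and a few genes lie beyond the axes.

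The comparison of refed with fasted islets asks which transcripts follow feeding. Of all tested genes 56.9% passed this test, so the counts of list members below are to be read beside that share. The amino acid and stress response genes under the factor ATF4 fell together after refeeding. Of the 25 measured members of that list, 24 fell, 0 rose and 1 did not pass, and all 25 fell adjusted over the list alone. Trib3, a pseudokinase gene on chromosome 2 at 152163161 to 152169796, fell by 3.28 ± 0.08 on the log2 scale (adjusted p = 1.5e-07), from an FPKM of 245 to 21.6 in WT and from 201 to 22.3 in KR. Ddit3, which encodes the stress factor CHOP and lies on chromosome 10 at 126727849 to 126733344, fell by 2.85 ± 0.09 (adjusted p = 4.84e-07), from 1102 to 131 in WT and from 735 to 117 in KR. Atf4 itself fell by 1.51 ± 0.06 (adjusted p = 1.65e-06), the glutathione-degrading enzyme gene Chac1 by 2.49, the amino acid transporter gene Slc7a5 by 2.05 and Asns, which encodes asparagine synthetase, by 0.27. The member that did not pass, named after its value was seen, was the cystine transporter gene Slc7a11, with a change of -0.36 ± 0.14 (adjusted p = 0.0505). The median ratio of the list was -1.44 in WT and -1.35 in KR, at percentile 0 of the random lists in each, and 17 members in WT and 16 in KR were at least 2-fold lower. Outside the list the amino acid transporter genes Slc1a4 and Slc6a9 fell by 2.66 and 2.62.

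Of 25 unfolded protein response genes 16 fell, 5 rose and 4 did not pass, with the same counts of 16 and 5 adjusted over the list alone. Herpud1, a gene of protein degradation at the endoplasmic reticulum, fell by 1.11 ± 0.06 and Hspa5 by 0.20 ± 0.05, whereas Sec61b, a translocon subunit gene, rose by 0.30 and Pdia6, a disulfide isomerase gene, by 0.23. The list median was -0.20 in WT and -0.26 in KR, at percentile 0.01 in each.

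Among the 26 beta-cell identity genes 16 rose with refeeding, 4 fell and 6 did not pass, with 16 and 4 adjusted over the list alone, at medians of 0.29 in WT and 0.23 in KR, percentiles 92.3 and 93.4 of the random lists. G6pc2 rose by 1.19 ± 0.06 (adjusted p = 4.58e-06) and Slc2a2 by 1.03 ± 0.08 (adjusted p = 2.13e-05), in both genotypes. The homeobox gene Isl1 rose by 0.96, Iapp by 0.56 and Pdx1 by 0.44, and Abcc8 and Kcnj11, which encode the subunits of the ATP-sensitive potassium channel, fell by 0.53 and 0.38. Ins1 had log2 ratios of -0.30 in WT and 0.61 in KR and no shared change that passed (0.15 ± 0.16, adjusted p = 0.444), and Ins2 had a ratio of -0.02 in WT. Txnip, which glucose induces, rose by 1.78 ± 0.07 (adjusted p = 1.55e-06), from an FPKM of 18.9 to 63.4 in WT and from 24.0 to 90.5 in KR. Among 26 granule and exocytosis genes 8 rose and 12 fell, by either count, among them Sytl4, up by 1.05, and Syt4, down by 0.90, and the list medians of -0.10 and -0.15 lay at percentiles 0.31 and 0.34.

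Of 32 fatty acid oxidation genes 13 rose, 6 fell and 13 did not pass, with 13 and 6 adjusted over the list alone. Cpt1a fell by 0.71 ± 0.07 (adjusted p = 6.71e-05), and Etfdh and Cpt2 rose by 0.51 and 0.43. The list medians of 0.07 in WT and 0.034 in KR turned to -0.09 and -0.10 where acinar genes were left out and the libraries rescaled to a common total, a setting that moved the median of all genes from 0.0042 in WT and -0.02 in KR to -0.14 in both. Of 18 fatty acid and triglyceride synthesis genes 6 rose, among them Acly, which encodes ATP citrate lyase, by 0.30 and the desaturase gene Scd2 by 0.64, and 5 fell, among them the desaturase gene Fads1 by 0.66, with 6 and 6 adjusted over the list alone. Of 22 cholesterol synthesis genes 11 rose, among them Pmvk by 0.55 and Idi1 by 0.49, and 5 fell, among them the squalene epoxidase gene Sqle by 0.33, with 12 and 5 adjusted over the list alone. Their median was 0.21 in WT and 0.13 in KR, at percentiles 98.7 and 96.1, and turned to -0.0035 in KR under the same rescaling. Of 27 FoxO target genes 8 rose and 12 fell, with 9 and 12 adjusted over the list alone. The insulin receptor substrate gene Irs2 fell by 0.72 ± 0.09 (adjusted p = 0.000211), Klf15 by 1.02 and Gadd45a by 1.04. Among the members that rose were Txnip, by 1.78, and Sesn1, by 0.73. The list medians were -0.16 in WT and -0.05 in KR, at percentiles 5.13 and 38.5. In neither genotype was the list thus set apart from random lists.

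Ribosomal protein and oxidative phosphorylation transcripts were higher in the refed libraries. Of 45 ribosomal protein genes 43 rose and 1, Rplp2, fell, by either count, and Rpl41 rose by 0.56. Their medians were 0.43 in WT and 0.41 in KR, at percentile 99.9 in each. Of 47 oxidative phosphorylation genes 42 rose and 0 fell, with 43 and 0 adjusted over the list alone, among them Ndufa4 by 0.81, Sdhd by 0.78 and Cycs, which encodes cytochrome c, by 0.80. Their medians were 0.44 and 0.33, at percentiles 99.99 and 99.1. Of 30 glycolysis and TCA cycle genes 18 rose and 3 fell, by either count, with the fumarase gene Fh1 up by 0.81, Idh3a up by 0.58 and Idh2 down by 0.29. Across the 11840 genes with a reference length, the change with refeeding also followed transcript length, with a median of 0.14 in the shortest 2368 genes and -0.13 in the longest 2368.

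Of 19 circadian clock genes 12 fell and 0 rose, with 12 down and 1 up adjusted over the list alone, at medians of -0.50 and -0.47 in WT and KR, percentiles 0.02 and 0. Nfil3 fell by 2.00 ± 0.11, Cry1 by 1.22 and Per2 by 0.92, and the labels give no clock time for either state. Of 15 glucocorticoid and fasting response genes 8 fell and 3 rose, by either count, with Mt2 down by 1.03, Mt1 by 0.63 and the glucocorticoid target Fkbp5 by 0.65. Of 16 interferon response genes 8 rose and 0 fell, by either count, among them Usp18 by 1.11 ± 0.08 and Oasl2 by 1.27, at medians of 0.42 and 0.28. Of 16 immediate early genes 5 rose, with Egr1 up by 1.79, and 8 fell, with Atf3 down by 1.76, by either count. Of 9 inflammatory genes 2 rose and 3 fell, by either count. Of 13 cell cycle genes 3 rose, among them Pcna by 0.39, and 1, Ccnd2, fell by 0.73, by either count, and the list median in WT of 0.04 turned to -0.09 under the rescaling to a common total. Of 10 disallowed genes 1 rose and 4 fell, by either count, with catalase (Cat) down by 0.92. Of 10 progenitor genes 5 rose and 2 fell, by either count, with Myc down by 2.12 ± 0.11.

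Markers of other cells moved with feeding as well. Of 9 endothelial genes 6 fell and 1 rose, with 7 and 1 adjusted over the list alone, at medians of -0.64 in WT and -0.38 in KR, and Plvap, an endothelial membrane protein gene, fell by 0.91. Of 16 stellate cell and fibroblast genes 10 fell and 2 rose, with 11 and 2 adjusted over the list alone, with the collagen gene Col1a1 down by 1.15 ± 0.12 and Acta2 up by 0.68. Of 18 macrophage genes 7 fell, with Cd74 down by 0.94, and 2 rose, by either count. Of 11 duct genes 7 rose, with the keratin gene Krt8 up by 0.88, and 1 fell, by either count. Of 16 alpha, delta and PP cell genes 5 rose, with pancreatic polypeptide (Ppy) up by 0.55, and 3 fell, by either count, and their WT median of 0.06 turned to -0.07 under the rescaling to a common total. Of 6 acinar genes 4 rose, with Cela1 up by 0.47, and 1, Bhlha15, fell by 1.07, by either count. None of 5 lymphocyte genes passed by either count. Of 4 adipocyte genes Pparg and Fabp4 fell, by 1.27 and 0.47, and 1 rose, by either count. Bpgm, of the red blood cell list, rose by 0.51, and Th, of neuron and glia, rose by 0.78. Of the 3 measured neuron and glia genes 1 rose and 1 fell, by either count. Of 4 Y-linked genes 3 rose, Eif2s3y by 0.43 among them, by either count. The RNAs Rmrp and Rpph1, which carry no poly-A tail, rose by 2.30 ± 0.07 and 1.73 ± 0.08, and the ribosomal RNA precursor Rn45s, named after its values were seen, had an FPKM of 1174 and 944 in the fasted and 2206 and 1682 in the refed WT and KR libraries.

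**Figure D3:**
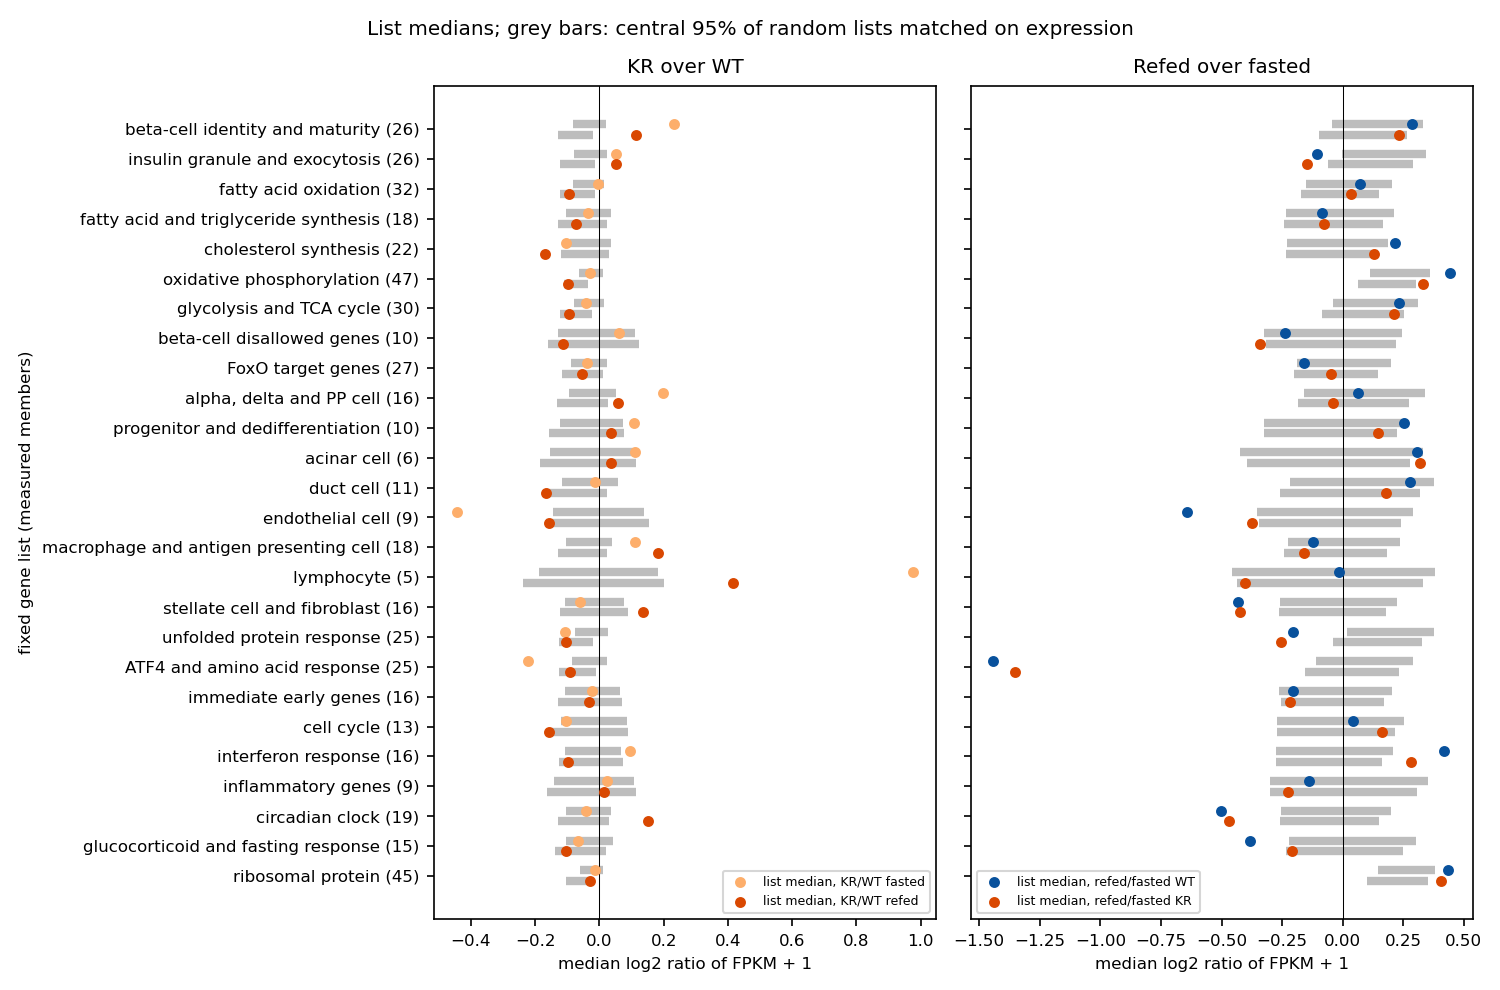
Median log2 ratio of FPKM + 1 for the 26 fixed lists with at least 5 measured members, KR over WT on the left and refed over fasted on the right, 1 point per pair of libraries. Grey bars span the central 95% of 10000 random lists matched on expression, and the ATF4 list at -1.44 and -1.35 after refeeding lies farthest from them.

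Of 11953 genes 6796 passed the limma test between feeding states, 3308 higher and 3488 lower after refeeding, or 56.9%, and 312 of them changed at least 2-fold. The median size of the called changes was 0.41 on the log2 scale. Among further leading genes, Tppp3 rose by 1.92 ± 0.08, the splicing factor gene Srsf3 by 1.96 ± 0.10 and the antimicrobial peptide gene Defb1 by 1.69, and Steap1 fell by 2.49, Akna by 2.46 and Areg, which encodes amphiregulin, by 2.43. Between single libraries, 420 genes differed at least 2-fold in WT (133 higher, 287 lower after refeeding) and 278 in KR (69 higher, 209 lower). Of these 215 moved in the same direction in both genotypes, 44 higher and 171 lower, against 0.768 and 5.02 for independent lists. In opposite directions moved 3, against 3.98 for independent lists. Across genes the ratios had a Pearson r of 0.78 and a Spearman rho of 0.87. The refed libraries were the shallower ones in both genotypes. The share of calls that were higher was 48.7%, and 50.6% with the libraries rescaled by the median of ratios. It was 29.6% where acinar genes were left out and the rest rescaled to a common total. That setting also leaves out Ins2, so the lower share cannot be laid to acinar genes.

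Whether the genotype difference itself changes with feeding could not be tested beside both main effects, since no residual degree of freedom is left. Fitted beside feeding alone it called 1 gene and beside genotype alone 2, but these fits count the other main effect as error. As values, the log2 ratio of KR to WT was larger in the refed than in the fasted pair by 0.92 for Ins1 and by 1.14 for Egr1, and smaller for Mafa, with a difference of -0.76, and for Pdx1, with -0.41. For Slc2a2 and G6pc2 the differences were -0.30 and -0.21, and for Cpt1a and Foxo1 they were -0.10 and -0.14. In each of the 4 contrasts, 11 of the 26 lists had a median outside the central 95% of random lists, but not the same 11. The circadian list lay outside for KR over WT in the refed pair, at 0.15 and percentile 100, and inside in the fasted pair, at -0.04, a difference that was not tested.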

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

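All tests in this part were chosen after the results they measure were seen, and the comparisons for transcript length, depth and reads of Ins2 were changed after their first outcomes were seen.

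Genes of the ATF4 and amino acid response were lower after refeeding in both genotypes. Lower depth of the refed libraries would need the larger fall in KR, whose refed library is the shallowest. The KR ratio minus the WT ratio had a median of 0.14 over the members (95% bootstrap interval 0.01 to 0.33). This lay above random lists matched on expression (median -0.04, central 95% -0.10 to 0.02), so the fall was not larger in KR. The same difference is the KR to WT ratio refed minus that fasted, and the list's medians of these were -0.09 and -0.22. A genotype difference that changes with feeding could thus move it too, so it argues against depth only as the whole cause. Stress of handling and isolation, higher in the fasted pools, cannot be told apart from feeding, because the immediate early genes, with a median change of -0.25, went both ways with an SD of 0.80 over members. An effect of feeding, untested apart from this, and any unrecorded difference between the pools stay open.

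Ins1 was higher in KR than in WT in both feeding states. A fixed share of Ins2 reads assigned to Ins1 could raise Ins1 by no more than the ratio of Ins2, and in the refed pair the log2 ratio of Ins1 exceeded that of Ins2 by 1.07 (1.04 to 1.10 from the deposited bounds), which argues against it, while a share that differs between libraries stays open. In the fasted pair, at 0.88 for Ins1, such reads cannot be told apart from a rise of Ins1, because Ins2 has no value in fasted KR. A larger share of beta cells in the KR pool would raise other beta-cell transcripts as much as Ins1. For this 9 were picked: Iapp, Ucn3, Nkx6-1, Pdx1, Slc2a2, G6pc2, Mafa, Trpm5 and Ero1lb. Their median was 0.23 (95% bootstrap interval 0.09 to 0.52) in the refed pair, where Ins1 was 3.49-fold higher. In the fasted pair it was 0.48 (0.19 to 0.84), where Ins1 was 1.84-fold higher, or 0.88. This argues against a larger share as the whole cause, in the fasted pair narrowly. A contribution of it stays open, since 8 of the 9 were higher in KR in the refed and 9 in the fasted pair. An effect of the KR genotype and an unrecorded difference between the pools stay open, neither of them tested.

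Ribosomal protein and oxidative phosphorylation transcripts were higher after refeeding. Both groups are short, and against random lists matched on expression and length their medians lay at percentiles 96.42 and 96.77, within the central 95%, while the pool held these families, and at 99.83 and 99.77 once it held neither, so length as the whole cause is argued against only by the changed comparison. Random lists had medians of 0.25 and 0.23 when matched on expression alone, 0.34 and 0.27 with length added from the first pool and 0.25 and 0.23 from the second, against 0.42 and 0.38 for the families. Lower depth of the refed libraries would need the larger rise in KR, and the ribosomal proteins had a median KR ratio minus WT ratio of 0.0027 (95% bootstrap interval -0.04 to 0.02), above random lists matched on expression (median -0.05, central 95% -0.08 to -0.02), so depth may contribute there. A genotype difference that changes with feeding would move this median as well, so it does not decide. For oxidative phosphorylation that median was -0.065 (-0.09 to -0.04), an interval below 0, so the rise was the smaller one in KR. Relative to all genes the list medians were 0.35 in KR and 0.44 in WT. However, the median of -0.065 lay inside the range of its random lists (median -0.05, central 95% -0.09 to -0.01). Other genes of the same expression thus behaved alike. A genotype difference that changes with feeding would move this median too, so it does not decide, and depth stays open there. For both families an effect of feeding and RNA quality stay open, beside rises of 2.30 in Rmrp and 1.73 in Rpph1, which carry no poly-A tail, and a Spearman rho of -0.23 between change and length.

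Another 5 genes, all of small RNAs, were at least 2-fold apart in opposite directions in the compared pairs, and no difference between the pairs was tested. Snora28 had a KR to WT ratio of -1.80 in the fasted and 1.70 in the refed pair, a difference of 3.50. Snora34 had 2.52 and -5.25, a difference of -7.77, and is listed at 0 in refed KR. Snora78 had 2.53 and -3.92, a difference of -6.45, and its refed to fasted ratios were 3.92 in WT and -2.53 in KR, again a difference of -6.45, with values listed at 0 in fasted WT and refed KR. Scarna6 had refed to fasted ratios of 1.22 in WT and -1.30 in KR, a difference of -2.52, and is listed at 0 in refed KR. Snora17 had -4.67 and 1.21, a difference of 5.88, and is listed at 0 in refed WT.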

How the results depend on the processing

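The results without small RNA genes and with limma-voom were computed after the data were seen. Of 151 genes past adjusted p 0.05 between genotypes in the additive model, the number was 0 with no filter on low values (1892 at an unadjusted p under 0.05), 5 in limma without trend, 95 with a pseudocount of 5, 228 with a robust prior, 252 at a mean FPKM of at least 5, 307 without small RNA genes and 892 with limma-voom, which shared 141. The other settings gave 137 to 191, and between feeding states every setting gave 5143 to 7455, against 6796. Genes 2-fold apart numbered, for KR over WT fasted and refed and for refed over fasted in WT and KR, 62, 93, 687 and 478 with a pseudocount of 0.1, and 11, 27, 196 and 136 with 5. Threshold changes gave 133, 170, 1925 and 1542 at 1.5-fold and 13, 22, 44 and 35 at 4-fold, since the threshold sets the count. The genotype pairs gave 14 and 24 at a mean FPKM of at least 5, and 17 and 23 without small RNA genes, as fewer genes were tested. Genes 2-fold apart in the same direction in both genotype pairs numbered 17 and 3 with pseudocounts of 0.1 and 5, 5 at a mean FPKM of at least 5, 7 without small RNA genes and 40 at 1.5-fold. Between feeding states they numbered 343 and 109 with pseudocounts of 0.1 and 5, and 1157 at 1.5-fold. At a mean FPKM of at least 5, 7 lists lay outside the central 95% for KR over WT fasted and 7 for refed over fasted in KR, against 11 each. Among list medians, progenitor genes in KR over WT fasted turned to -0.014 at a mean FPKM of at least 5, and ribosomal proteins in KR over WT refed turned to 0.028 after rescaling by the median of ratios, which moved all genes alike (the list relative to all genes was 0.024 and then 0.029). A set of 60 genes, from the fixed panel and the rankings but not those named only as list members, was followed. Of these, 28 lost their genotype call without trend and 6 their feeding call. The other 32 of the genotype test include genes with no call to lose, since limma without trend called 5 genes in all. Among the 60, limma-voom brought 14 past the genotype threshold, Foxo1 among them, and took 3 off. Except where fewer genes were tested or the threshold moved, the cause was not tested. Leaving out a library leaves no residual degree of freedom, so it was not run. No paired analysis was possible because each group has 1 pooled library and the labels pair no animals. The refed KR library, at 0.418 of the depth of fasted WT, limits low genes most, and alternatives for raw counts were not run, as the files hold FPKM.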

Other observations

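In this part the synthetase test was chosen after the result was seen, and the test around Foxo1 was not.

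Transcripts of the enzymes that load amino acids onto transfer RNA fell with refeeding in 13 of 20 cytosolic members and rose in 4. This list was written after the ATF4 genes were seen. Yars, which encodes the tyrosine enzyme, fell by 1.55 ± 0.06 on the log2 scale (adjusted p = 1.71e-06), and Cars, the cysteine enzyme, by 1.36 ± 0.08, while Dars, the aspartate enzyme, rose by 0.46 ± 0.06. Of the 17 mitochondrial enzymes 4 rose and 4 fell, with a median of -0.01 against -0.54 for the cytosolic ones. The difference of medians was -0.53 (p = 0.0266, 100000 permutations across genes), and genes are not independent samples. Most mitochondrial members had a lower FPKM than most cytosolic ones, and log2(FPKM + 1) understates the change of low genes. The sets were not matched on expression, so part of the difference may come from this scale.

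A few low genes with the largest shared genotype differences were chosen after their values were seen. Cxcl13, which encodes a chemokine that draws B cells, had an FPKM of 0.844 and 5.68 in fasted and 1.12 and 3.94 in refed WT and KR islets, and rose by 1.54 ± 0.16 (adjusted p = 0.00391). Cnr1, the cannabinoid receptor gene, rose by 1.05 ± 0.12 (adjusted p = 0.0065), the tight junction gene Cldn11 by 1.07 ± 0.10 (adjusted p = 0.0026) and the X-linked gene Xlr4a by 1.42 ± 0.16 (adjusted p = 0.00523).

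A chromosome segment carried along with the knocked-in allele would, if it changed its own genes, place many genotype calls near Foxo1. Within 20 Mb of it lay 1 of the 151 called genes, or 0.662%, against 0.862% of the tested genes (Fisher's exact p = 1). Most calls were thus not genes of such a segment within this window. Effects of a segment on genes elsewhere were not tested. On the whole of chromosome 3, where Slc2a2 lies outside that window, were 10 called genes, or 6.62%, against 4.81% of the tested genes.

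Ins2 in fasted KR can be estimated if depth there followed that of the other genes. With each of the other libraries as reference, the fragments then missing would put its FPKM at 153315, 168250 and 167748, at log2 ratios to fasted WT of 0.32, 0.45 and 0.45. These estimates are no bounds, rest on the assumption and were not tested.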
